A study of Mus musculus with 7 samples.

How the data were processed

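The series holds 7 bulk RNA-seq libraries of tdTomato-expressing cells sorted from mouse skin on day 36, 3 controls and 4 Zfp750 knockouts. Per the labels' protocols, RNA was extracted with a PureLink kit and libraries were made with the NEBNext Ultra II kit. TopHat2 2.1.0, a spliced aligner, and Partek 9.0.20.0202, an analysis platform, are named per the submitters' processing notes. The genome build and the strand setting of the counting are not given in the sources used here.

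The authors deposited 1 table of normalized counts for 25322 genes, and its values are a signal, not raw counts. Per the file headers the values are normalized counts. Tested on the deposited values, each column is a set of partly estimated read counts divided by 1 factor per library. Between 78.0% and 79.6% of values under 200 reads were whole multiples of that step, within a tolerance of 0.02 reads, and the rest were fractional. Whole reads were therefore not recovered, and the count tests planned for that case were not run. Median-of-ratios size factors computed from the same values were 0.998 to 1.001 times these factors. The fewest reads summed over the libraries for a listed gene were 10, so rarer genes are missing. Read totals recovered with the steps were 17.1, 9.09 and 9.97 M in control 4F, 4M and 7F and 12.9, 13.6, 9.55 and 15.2 M in Zfp750_KO 1M, 2M, 3F and 6F. Positions in the deposited table match the GENCODE M21 annotation for the starts of all 15 mitochondrial genes but for 533 of 24484 other genes, so its nuclear coordinates were not mixed with that annotation, and chromosomes and gene identifiers alone are given.

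The columns carry short names that state the group but match no single sample title. They were assigned to the groups by these names, without replicate numbers. The control given as wild type for Zfp750 and the knockout given as Rosa26 -/- could therefore not be tied to columns. The letters M and F in the names were read as male and female for a sex term and for a test of genotype by sex. No pair of libraries looked like a repeat of the same library: the share of genes over 20 reads that differed beyond counting noise was 39.4% to 76.8% over the pairs.

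Values were analysed as log2(value + 11.9), where the pseudocount is 1 per M of the median column total. A log2 difference on this scale understates the change of genes with low values. Genes with at least 1 per M of the column total in at least 3 libraries were tested, 18141 in all. The planned test was limma 3.58.1 in R 4.3.3, with lmFit and eBayes with a trend, the group as the only term and Benjamini-Hochberg adjustment at 0.05. Zfp750 was also tested by a two-sided exact permutation over 35 splits. The 28 gene lists fixed before the data were examined were tested with camera (preset correlation 0.01), again with the correlation estimated, and with fry. A further list of sex-linked genes was described but not tested.

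The named genes follow a rule fixed before the data were examined. Zfp750 and Lrig1 are always named. The 12 largest rises and the 12 largest falls are named among genes past the threshold whose groups do not overlap, with a mean of at least 5 per M in the higher group, without predicted genes. Where fewer than 5 genes pass, the 10 with the smallest p are named. In each list up to 4 members past the threshold with the largest difference are named, or else the 2 with the highest mean, of which the text prints at least some. The same rule was applied to the second fit below.

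After seeing the data, a second limma fit was added with the macrophage score as a covariate. The score is the mean log2 value of 21 tested genes of the macrophage and monocyte list, so estimates for those genes are relative to their own mean. This leaves 4 residual degrees of freedom, against 5 with the group term alone. Both fits were tested on simulated data. Without a composition trend, on 17612 genes of which 100 changed 2-fold and 100 changed 4-fold, the fit with the group alone recovered 62% and 100%, and 4.14% of its calls were false, against 61%, 100% and 5.29% with the score. A trend in composition was then simulated as linear in the macrophage score, with the slopes of the real libraries, on 17562 genes. There the fit with the group alone recovered 0% and 10%. The fit with the score recovered 59% and 100%, with 3.64% false calls. The simulated trend has the form that this fit assumes, and changes were equal in all Zfp750_KO libraries. Noise had the same dispersion in all simulated genes, and changes were placed only in genes above a minimum mean level. The recovered shares hold for these settings alone. The simulation therefore cannot tell how many calls are false or missed in the real libraries.

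Alternatives planned beforehand were other pseudocounts, filters and scalings, robust moderation, array weights, a log2 threshold of 1, leaving out each library, and other set tests. Terms for sex, the macrophage score, a fibroblast score and the first principal component were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.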

Results

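Gene expression was measured by bulk RNA-seq in cells sorted from mouse skin on day 36. Zfp750 is the mouse counterpart of human ZNF750, a transcription factor of epidermal terminal differentiation. Per the labels, all mice carried a tamoxifen-inducible Cre recombinase driven by Lrig1, a gene of stem cells in the junctional zone of the hair follicle, and cells expressing the red reporter tdTomato were sorted. The knockouts are given as floxed on both Zfp750 alleles, 2 controls as floxed on 1 allele and 1 control as wild type, and 1 knockout is given as Rosa26 -/- where the others are +/-. 4-hydroxytamoxifen was given from day 4 to 7 or from day 5 to 8 of age. The 7 libraries were 3 controls and 4 Zfp750 knockouts (Zfp750_KO). The columns of the deposited table carry their own short names, and the libraries are called by them here: control 4F, 4M and 7F, and Zfp750_KO 1M, 2M, 3F and 6F. The labels do not say whether each library came from its own animal, so p-values measure the spread between these libraries. The read totals recovered from the values were 9.09 to 17.1 M reads per library.

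The comparison of Zfp750_KO with control asks how gene expression in the labelled skin cells differs after loss of Zfp750. The targeted gene itself (ENSMUSG00000039238, chromosome 11) was lower in all 4 Zfp750_KO libraries than in any control. Its normalized values were 335, 51.2 and 61.9 in control 4F, 4M and 7F, and 48.9, 45.4, 10.1 and 29.6 in Zfp750_KO 1M, 2M, 3F and 6F. The mean was 149 ± 161 (SD, n = 3) in controls and 33.5 ± 17.7 (SD, n = 4) in Zfp750_KO. On the log2(value + 11.9) scale the difference was -1.47, with a two-sided exact permutation p = 0.0571, which is the smallest that the 35 splits of 7 libraries allow. It was -0.69 without control 4F. In the limma fit over all genes its adjusted p was 0.891. Relative to Krt5, a keratin of basal keratinocytes, Zfp750 stood at 2.28% to 5.14% in controls and at 0.401% to 1.79% in Zfp750_KO. The Zfp750_KO libraries still held 9 to 47 reads of Zfp750. The gene lies inside Tbcd on the opposite strand, and the sources used here give neither the strand setting of the counting nor the deleted exons. Lrig1 (ENSMUSG00000030029, chromosome 6) had means of 860 ± 617 (SD, n = 3) and 1033 ± 767 (SD, n = 4), with a log2 difference of 0.10 ± 0.74 (SE) and an adjusted p of 1.0. Its normalized values were 1570, 536 and 472 in control 4F, 4M and 7F. In Zfp750_KO 1M, 2M, 3F and 6F they were 1620, 1770, 300 and 445. Control 4F and Zfp750_KO 1M and 2M, the higher ones, are also the libraries with the lower macrophage scores given below.

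**Figure D1:**
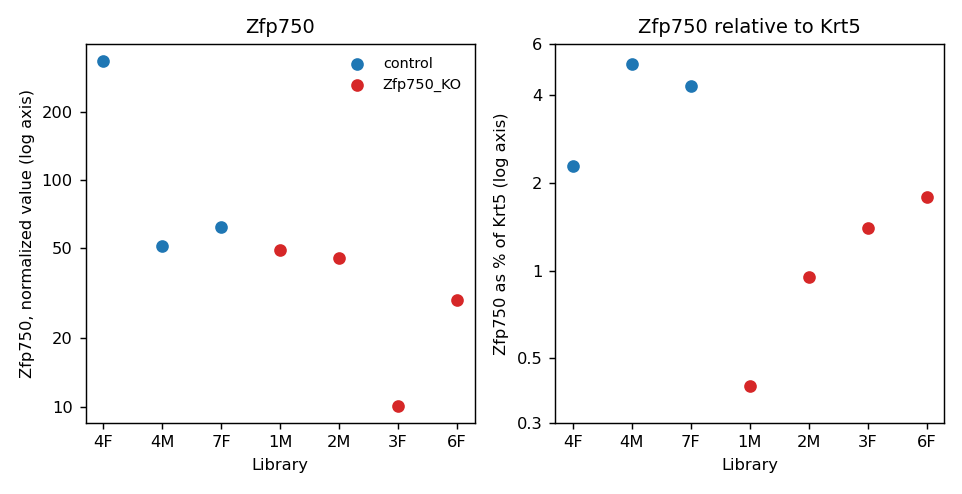
Normalized value of Zfp750 (left, log axis) and Zfp750 as a percentage of Krt5 (right, log axis) in each of the 7 libraries, with 1 point per library. The 4 Zfp750_KO libraries lie between 10.1 and 48.9, below the lowest control at 51.2.

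The libraries differed widely in immune and epithelial transcripts, within both groups. The mean log2 level of 21 macrophage and monocyte genes, called the macrophage score here, was 5.76 in control 4F against 10.6 and 10.8 in control 4M and 7F. In Zfp750_KO it was 7.36 and 6.99 in 1M and 2M against 11.5 and 11.2 in 3F and 6F. Ptprc, the leukocyte antigen CD45, ranged from 4.46 per M of the library total in control 4F to 1250 per M in Zfp750_KO 3F. Cd74, the invariant chain of MHC class II, ranged from 72.7 to 8940 per M, and Krt5 from 67.5 to 1110 per M. Col1a1, a collagen of fibroblasts, was the most abundant gene in 6 of the 7 libraries and took 0.548% of the total in Zfp750_KO 3F and 8.1% in control 4F. The first principal component held 68.3% of the variance and followed this difference, whereas the second held 14% and placed all controls on one side and all Zfp750_KO libraries on the other. Between the groups the macrophage score differed by 0.21 (two-sided exact permutation p = 0.8), and the mean of the fibroblast list by -0.14 (p = 0.857 by the same exact test).

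**Figure D2:**
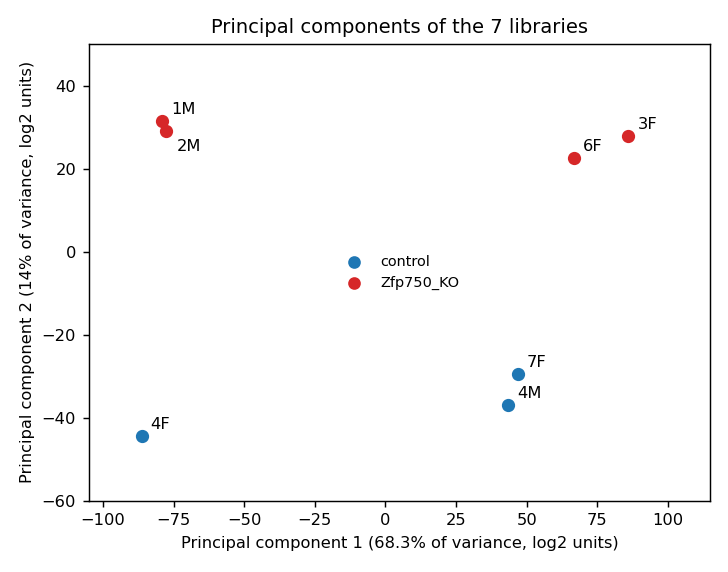
Principal components 1 and 2 of the log2 values of 18141 genes in the 7 libraries, in log2 units, with 1 point per library. Controls lie between -44.4 and -29.4 on component 2, and Zfp750_KO libraries between 22.4 and 31.4.

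**Figure D3:**
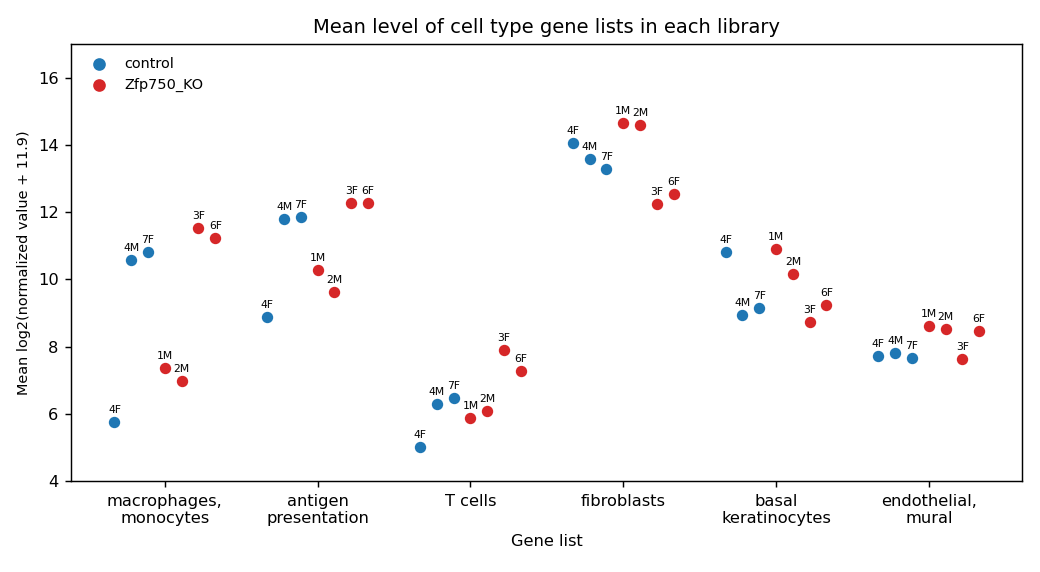
Mean log2(normalized value + 11.9) of the tested members of 6 gene lists in each library, with 1 point per library. The macrophage and monocyte mean runs from 5.76 to 11.5 and spans both groups.

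No gene passed an adjusted p of 0.05 in the planned limma fit with the group as its only term, in either direction, of 18141 tested. At an unadjusted p under 0.05 there were 1058 genes, or 5.83%, and the smallest adjusted p was 0.104. By the rule fixed before the data were examined, the 10 genes with the smallest p were taken up, none of them past the threshold, and 9 of them are described here. Igfbp6, an insulin-like growth factor binding protein, had normalized values of 1504 ± 283 (SD, n = 3) in controls and 324 ± 82.0 (SD, n = 4) in Zfp750_KO, a log2 difference of -2.20 ± 0.26 (SE). Entpd2, an ectonucleotidase, differed by -1.85 ± 0.22. Dapk1, a death-associated kinase, differed by -1.23 ± 0.15 and Glt8d2 by -2.30 ± 0.28. In the other direction, Cxcl5, a chemokine that attracts neutrophils, was at 1.27 ± 1.15 in controls and 97.8 ± 40.1 in Zfp750_KO, a log2 difference of 2.98 ± 0.35. Nrg1, a ligand of ERBB receptors, differed by 2.87 ± 0.35, the adhesion molecule Chl1 by 2.74 ± 0.33, Smim3 by 2.19 ± 0.27 and the transcription factor Ets1 by 1.42 ± 0.17. In all 9 genes every Zfp750_KO library lay beyond every control, as it did in 579 genes higher and 709 genes lower in Zfp750_KO. These are 7.1% of the genes tested, where chance gives 5.71%.

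**Figure D4:**
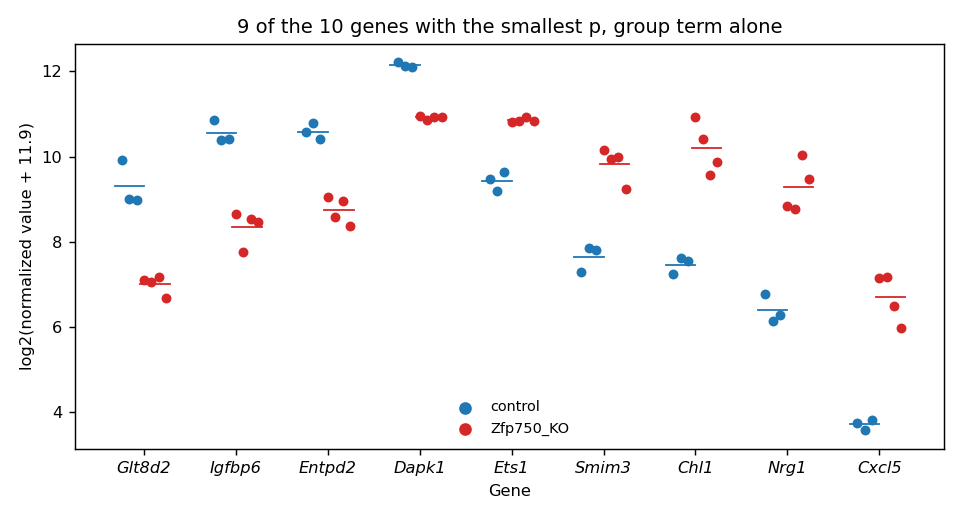
Log2(normalized value + 11.9) of 9 of the 10 genes with the smallest p in the fit with the group term alone, with 1 point per library and a line at each group mean. The points of the groups do not overlap in any of these genes, and the adjusted p is 0.104 for each.

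Because the macrophage score varied within both groups, a second fit, chosen after seeing the data, held it as a covariate. In that limma fit 228 genes were higher and 366 lower in Zfp750_KO at an adjusted p under 0.05. Of these, 107 and 225 separated the groups without overlap. The counts depended on single libraries: they were 620 and 1049 without control 4F, 48 and 89 without control 4M, and 58 and 95 without control 7F. Zfp750 had a log2 difference of -1.40 ± 0.31 (SE) there, with an adjusted p of 0.0474; of the 7 fits without 1 library it passed only in that without Zfp750_KO 6F (adjusted p = 0.0243), and was at -1.02 without control 4F. The values in the following paragraphs come from this fit.

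Mmp13, a collagenase, led the 12 largest rises. It rose by 4.74 ± 1.06 on the log2 scale (SE, adjusted p = 0.048), from 24.0 ± 4.77 (SD, n = 3) to normalized values of 8728, 3510, 177 and 85.4 in Zfp750_KO 1M, 2M, 3F and 6F. Timp1, an inhibitor of matrix metalloproteinases, rose by 2.31 and Mmp8, a collagenase of neutrophils, by 2.29. Cxcl5 rose by 3.00, Nrg1 by 2.86 and Chl1 by 2.75. Prdm1, a transcriptional repressor found in sebaceous and terminally differentiating epidermal cells among others, rose by 2.66. Cbln1 rose by 3.47, Sv2c by 2.57, Kcns1 by 2.49, Tnfrsf11b, a decoy receptor for RANKL, by 2.25, and the uridine kinase Uck2 by 2.22. Adjusted p-values of these 12 genes lay between 0.00332 and 0.048. The levels were uneven within Zfp750_KO: Tnfrsf11b was at 1363 and 1291 in 1M and 2M against 172 and 161 in 3F and 6F, with 88.9 to 110 in controls, and Mmp13, Cbln1, Kcns1, Sv2c, Timp1, Prdm1, Uck2, Chl1 and Cxcl5 were also higher in 1M and 2M than in 3F and 6F. Nrg1 was higher in 3F and 6F, and Mmp8 was mixed. The fit assumes the same slope on the macrophage score in both groups, and Mmp13 and Tnfrsf11b depart from it. Both varied little over the controls, whose scores ran from 5.76 to 10.8. In Zfp750_KO both were far higher in 1M and 2M, which had the lower scores of that group. Their log2 differences, SE and adjusted p-values therefore do not describe all Zfp750_KO libraries alike. Without control 4F the log2 difference was 2.73 for Mmp13, 1.63 for Sv2c and 1.27 for Tnfrsf11b.

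Among the 12 largest falls, Esr1, an estrogen receptor, had a log2 difference of -2.51 ± 0.31 (SE, adjusted p = 0.00494), from 2383 ± 229 (SD, n = 3) to 464 ± 220 (SD, n = 4). Oxtr, the oxytocin receptor, differed by -2.58. Scara5, a ferritin receptor, differed by -2.68, the secreted Wnt modulator Sfrp4 by -2.58, and the matrix protein Spon2 by -2.37. Aldh1a1, a retinaldehyde dehydrogenase, differed by -2.54, the cytochrome P450 Cyp2f2 by -3.61 and the carboxylesterase Ces2g by -2.51. Myog, a transcription factor of myoblasts, differed by -2.71, the imprinted RNA H19 by -2.40, Opcml by -2.83 and Lrrtm4 by -2.37. Adjusted p-values of these 12 genes were 0.00332 to 0.0285.

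**Figure D5:**
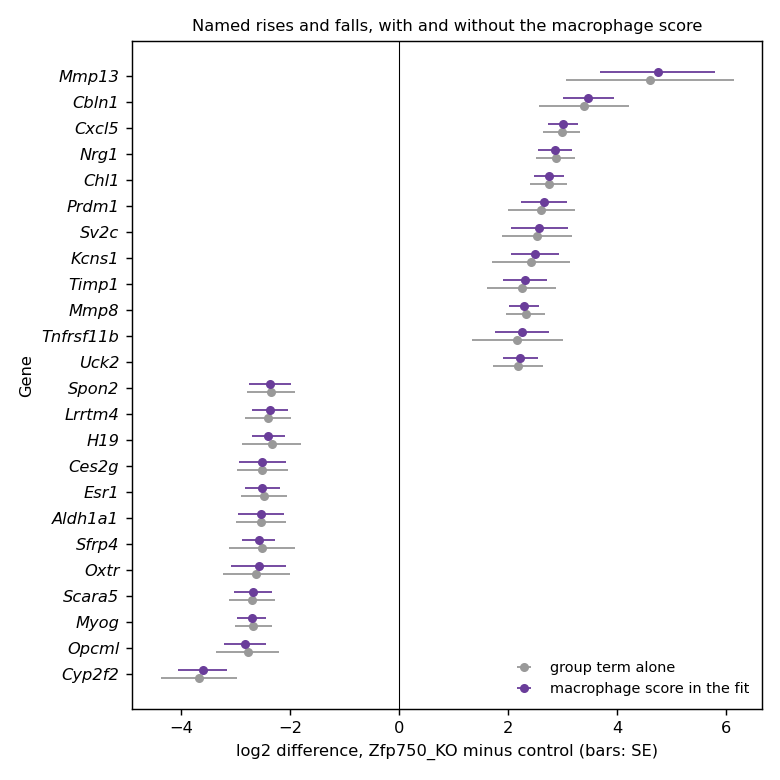
Log2 difference, Zfp750_KO minus control, of the 12 largest rises and the 12 largest falls, with the macrophage score in the fit (purple) and with the group term alone (grey). Points are estimates and bars are SE, and the estimates run from -3.61 for Cyp2f2 to 4.74 for Mmp13 with the score.

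Of these 24 genes, 14 stayed past the threshold without any 1 of the 7 libraries. The other 10 each lost the call in at least 1 such fit: Mmp13, Prdm1, Sv2c, Kcns1, Timp1, Tnfrsf11b, Oxtr, Aldh1a1, Ces2g and Spon2. Of 44 further genes that passed and that the naming rule took from the gene lists, 12 kept the call in all 7 fits and 32 did not. Cxcl5, Nrg1, Chl1, Uck2, Cyp2f2, Opcml, Myog, Scara5, Sfrp4, Esr1, Fads6 and Cd34 kept it in all 19 alternative settings, and Cbln1, Mmp8 and Lrrtm4 in the 18 in which they were tested.

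Gene lists fixed before the data were examined were compared next, first for inflammation and keratinocyte stress. In this limma fit 3060 of the 18141 genes tested, or 16.9%, had an unadjusted p under 0.05. Counts adjusted over a list alone are to be read beside this share. Of the 45 members of the psoriasis-type stress list, 15 could be tested. Of these, 3 rose, none fell and 12 did not pass. Adjusted over the list alone, 9 rose and 1 fell. Slpi, a protease inhibitor of inflamed epithelia, rose by 2.15, Lcn2, a siderophore-binding protein, by 2.09, and the cross-linking enzyme Tgm1 by 1.20. Among 27 keratinocyte cytokine and chemokine genes 3 rose, namely Cxcl5, Cxcl16 by 1.45 and Il1b by 1.02, and adjusted over the list alone 5 rose and 1 fell. Cxcl16 and Il1b overlapped between the groups, and with the group term alone their adjusted p was 0.882 and 1.0. Il1b was at 38.7 in control 4F and 8380 in Zfp750_KO 3F, the libraries with the lowest and the highest macrophage score, so its level is not that of keratinocytes alone. None of 35 interferon response genes passed, adjusted over all genes or adjusted over the list alone, and Parp14 was at 0.037 ± 0.14 (SE). In the camera set test with the group term alone the stress list was higher (adjusted p = 0.000193) and so was the cytokine list (adjusted p = 0.02). With an estimated correlation the adjusted p was 0.606 and 0.505, and the cytokine list was at 0.303 without control 4F and at 0.436 with array weights. With a filter of 5 per M the adjusted p was 0.0995 for the stress list, whose mean difference moved from 0.84 to 0.46, and 0.133 for the cytokine list. Slpi, Lcn2, Tgm1, Cxcl16 and Il1b lost their calls without control 4M and without control 7F, with adjusted p-values up to 0.118, and Slpi was at 1.38 without control 4F.

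Cholesterol synthesis had 6 of 25 measured genes higher and none lower, and adjusted over the list alone 15 were higher. The synthesis enzymes Cyp51, Msmo1 and Idi1 rose by 1.10, 0.90 and 0.85. Glycolysis and hypoxia had 4 of 26 genes higher and none lower, and 14 higher when adjusted over the list alone. Egln3, a prolyl hydroxylase induced by hypoxia, rose by 1.28, Ndrg1 by 1.06, the glucose transporter Slc2a1 by 0.90 and the pyruvate kinase Pkm by 0.72. With the group term alone the camera adjusted p was 9.33e-11 for cholesterol synthesis and 1.42e-07 for glycolysis and hypoxia. With an estimated correlation the adjusted p was 0.246 and 0.0775. In fry the adjusted p was 0.144 and 0.00907 with the group term alone. With the macrophage score the fry adjusted p was 0.0247 and 0.0146. Idi1 and Pkm lost their calls in 6 of the 7 fits without 1 library, all but that without control 4F, Msmo1 and Slc2a1 without control 4M or 7F, and Cyp51 without control 4M.

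Epidermal, sebaceous and hair follicle lists had few members past the threshold. Tested were 22 of 47 cornified envelope, 19 of 25 barrier lipid, 32 of 41 sebaceous and 24 of 42 hair shaft genes. The libraries held little keratin RNA beside collagen. Per M of the library total, Krt14 was at 40.1 to 608 and Krt10 at 0.523 to 11, against 5480 to 81000 for Col1a1. The few calls therefore do not show that keratinocytes were unchanged. The cornified envelope list had 2 of 22 genes higher, Prdm1 and Tgm1, and 1 lower, Ppl, an envelope plakin, by -0.93; adjusted over the list alone 6 were higher and 5 lower. None of 19 epidermal barrier lipid enzymes passed under either adjustment, and Ugcg, the glucosylceramide synthase, was at 0.73 ± 0.24 (SE). Of 32 sebaceous genes 2 fell, among them Fads6, a fatty acid desaturase, by -1.81, and adjusted over the list alone 1 rose and 2 fell. Scd1 and Fasn, the members of the list with the highest means, had log2 differences of -0.30 ± 0.39 and -0.21 ± 0.16 (SE). In the junctional zone list of 13 genes Nebl rose by 1.55 and Ly6a, the surface antigen Sca-1, had a difference of -0.93; adjusted over the list alone 3 rose and 2 fell. In the bulge list of 26 genes Runx1 rose by 1.19, while Cd34 differed by -1.63, and adjusted over the list alone 1 rose and 3 fell. Il31ra was at -1.14 and lost its call without any 1 of the 7 libraries, with adjusted p-values up to 0.142. Cd34 and Ly6a are also genes of dermal fibroblasts. Of 24 hair shaft and inner root sheath genes 3 fell, the keratins Krt75 by -2.06, Krt28 by -1.37 and Krt71 by -1.06, and the count adjusted over the list alone was 3. This list was lower in the camera test with the group term alone (adjusted p = 5.78e-07, or 0.606 as the adjusted p with an estimated correlation, 0.125 without control 4F and 0.703 with array weights). Fads6 and Cd34 kept their calls without any 1 library. Of the others, Prdm1 and Runx1 lost theirs in 1 of the 7 fits without 1 library, Tgm1 and Nebl in 3, Ly6a and Krt75 in 4, and Ppl, Krt28 and Krt71 in 5, with the control 4M or 7F fit among them for each.

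In the endothelial and mural list of 18 genes the contractile genes Tagln, Acta2, Myh11 and Mylk rose by 2.17, 1.49, 1.24 and 1.17, and Tek, an endothelial receptor, differed by -1.42; adjusted over the list alone 7 rose and 3 fell. Of 20 T cell genes 3 rose, among them Il2rb by 1.43 and Trac by 1.25. Adjusted over the list alone 12 rose, but all 20 overlapped between the groups. Mmp8 was the 1 of 7 neutrophil genes that passed, and adjusted over the list alone 4 rose and 1 fell. Among 21 macrophage and monocyte genes, the list that makes up the score, Lyz1 differed by -2.26 and Cd163, a scavenger receptor of tissue macrophages, by -2.05; adjusted over the list alone 1 rose and 2 fell. Of 16 Langerhans and dendritic cell genes Itgax rose by 1.33 and Cd209a differed by -1.28, with 3 higher and 3 lower when adjusted over the list alone. The fibroblast list had 1 of 20 genes lower, Mfap5 by -1.01, and adjusted over the list alone 1 rose and 1 fell. In the list of muscle, fat, mast, blood and Merkel cells 6 of 12 genes fell and none rose, and 7 fell when adjusted over the list alone. Acta1, the actin of skeletal muscle, differed by -3.39, Myh4 by -2.91, Ckm by -2.76 and Car3 by -2.57. The T cell list (adjusted p = 8.25e-05), the neutrophil list (0.0429) and the endothelial and mural list (0.0124) were higher, and the muscle list (0.00092) lower, in camera with the group term alone. Each of these 4 lists had an adjusted p of 0.606 with an estimated correlation, and each lost its call without at least 1 library: without control 4F the T cell list was at 0.0913, the neutrophil list at 0.227 and the endothelial and mural list at 0.0584, and without control 7F the muscle list was at 0.054. With array weights the T cell and neutrophil means turned to -0.19 and -0.10 (adjusted p = 0.729 and 0.988). The T cell and muscle lists also lost it with a filter of 5 per M (0.133 and 0.229). Tagln, Acta2, Myh11, Mmp8, Lyz1, Cd163 and Acta1 kept their calls without any 1 library. Trac lost its call in 6 of these 7 fits, Tek, Itgax, Mfap5 and Car3 in 5, Myh4 in 2, and Il2rb, Cd209a and Ckm in 1, for each in that without control 4M, control 7F or both.

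The remaining lists held few or no calls. Basal keratinocyte genes had Ass1 higher by 1.21 and Mt1 at a difference of -0.88 among 21, the NRF2 list had Gstm1 at -1.23 among 22, and the antigen presentation list had Nlrc5 higher by 0.68 among 15. Ass1, Mt1 and Nlrc5 lost their calls in 5 of the 7 fits without 1 library and Gstm1 in 4, those without control 4M and 7F among them. The wound response list of 23 genes held Mmp13 and Timp1, and the melanocyte and Schwann cell list of 13 held 1 lower gene. Adjusted over the list alone, the counts higher and lower were 1 and 1 for basal keratinocytes, 2 and 3 for NRF2, 1 and 0 for antigen presentation, 5 and 0 for wound response, and 0 and 1 for melanocytes and Schwann cells. No gene of the proliferation (38), endoplasmic reticulum stress (22), dissociation (24), mitochondrial (13) and ribosomal protein (35) lists passed, also when adjusted over the list alone. Ccnd1, a cyclin, was at -0.71 ± 0.19 (SE), the chaperone Hspa5 at -0.38 ± 0.19, mt-Co1 at 0.57 ± 0.37 and Rplp0 at 0.21 ± 0.17. The dissociation genes Fosb and Fos, which handling of tissue can induce, differed by -0.63 ± 0.28 and -0.46 ± 0.28 (SE).

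In total the camera test with its preset correlation called 11 of the 28 lists with the group term alone, 8 higher and 3 lower, and 12 with the macrophage score, 10 higher and 2 lower. The calls not yet named were the wound response list (adjusted p = 0.0242), the mitochondrial list (0.0199) and the ribosomal protein list (0.000281), higher with the score, each at an adjusted p of 0.564 with an estimated correlation. The wound response list lost this call without control 4F (0.0741) or Zfp750_KO 1M (0.203), and the mitochondrial list without control 7F (0.111). With the group term alone they were proliferation, lower (adjusted p = 0.0272), and the ribosomal protein genes, higher (0.0147), both at an adjusted p of 0.913 with an estimated correlation. Proliferation lost its call without control 4F (0.493), Zfp750_KO 1M (0.474) or 2M (0.306), with a sex term (0.248), quantile normalization (0.0874) or the first principal component (0.0528), and the ribosomal protein list without control 4M (0.297), 7F (0.684), Zfp750_KO 1M (0.258) or 2M (0.112). None of the 28 lists passed with an estimated correlation in either fit. With the group term alone no list held a member past the threshold over all genes. Adjusted over the list alone, that fit called 3 genes of the stress list, 3 of cholesterol synthesis, 2 of the cornified envelope and 1 each of cytokines, bulge and neutrophils higher, and 2 sebaceous genes, 1 melanocyte and Schwann cell gene and 1 muscle list gene lower.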

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

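The tests of genotype by sex were chosen after the data were seen, and the search for libraries that stand apart within a group followed a rule set beforehand. A genotype by sex interaction was tested in limma with the sex read from the column names, which leaves 3 residual degrees of freedom. Its male-named control arm is a single library, control 4M, which is assumed to vary like the other libraries. The test passed an adjusted p of 0.05 for 3 of 18141 genes in limma, each at 0.0325, with 5252 genes at an unadjusted p under 0.05, and none of them is taken as a sex effect. Spon1, a secreted matrix protein, had an interaction of 5.53 on the log2 scale. Its normalized values were 18180 and 13960 in Zfp750_KO 1M and 2M, 349 and 483 in Zfp750_KO 3F and 6F, and 511 to 645 in the controls. Mmp11, a matrix metalloproteinase, had an interaction of 4.83, with 14580 and 14800 in Zfp750_KO 1M and 2M and 348 to 941 in the other 5 libraries. The male-named Zfp750_KO libraries are also those with the lower macrophage scores in their group, so sex and cell composition are not separated in Zfp750_KO. Xist, the RNA of the inactive X chromosome, had an interaction of -8.41. It stood at 3318 in control 4M against 46440 in control 7F, and at 6.24 and 0.966 in Zfp750_KO 1M and 2M. Ddx3y, a gene of the Y chromosome, was at 810 in control 4M and at 950 and 979 in Zfp750_KO 1M and 2M. Control 4M thus held a Y-linked gene near the level of the male-named Zfp750_KO libraries together with Xist far above theirs, so it did not look like a library of male cells alone. The Xist value follows from this library, and the sex term and the interaction both rest on it as the only male-named control.

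Within the 4 Zfp750_KO libraries, 4 of 152 results had a library far from the other 3, where chance gives about 1 in 20. That is fewer than this share, but the share assumes 4 independent libraries of 1 kind. Zfp750_KO 1M and 2M lay at -79.0 and -77.6 on principal component 1, against 86.0 and 66.6 for 3F and 6F. The share therefore cannot decide here, and chance is not excluded. Opcml was at 29.9 in Zfp750_KO 2M and at 158 to 178 in the other 3, and H19 at 168 in the same library against 294 to 309. Mt1, a metallothionein, was at 886 in Zfp750_KO 1M and at 585 to 588 in the others. The mean log2 level of the endothelial and mural list was 7.63 in Zfp750_KO 3F and 8.48 to 8.62 in the others.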

How the results depend on the processing

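The terms for both scores, sex and the first principal component, and all alternatives of the macrophage score fit, were chosen after seeing the data. With the group term alone, 0 genes passed in either direction under each pseudocount, filter, scaling, robust moderation, sex term, log2 threshold and left-out library. Array weights gave 1883 higher and 1912 lower genes, 197 of them in lists, and 19 lists, but the cytokine (adjusted p = 0.436), hair shaft (0.703), T cell (0.729) and neutrophil (0.988) lists lost their calls. Their weights were 3.99 for control 7F, 2.94 for Zfp750_KO 2M and 0.265 to 0.325 for control 4F, Zfp750_KO 3F and Zfp750_KO 6F. The fibroblast score gave 223 higher and 197 lower genes (28 in lists), the first principal component 410 and 476 (79 in lists), and the macrophage score 228 and 366 (55 in lists). Zfp750 passed with the first principal component (-1.50, adjusted p = 0.0431) and the macrophage score (-1.40, adjusted p = 0.0474). Its direction held in every setting that tested it, which the filter of 5 per M did not, at -0.49 with array weights and at -1.92 to -0.69 without 1 library. The 11 lists called became 7 with the filter of 5 per M, where fewer genes are tested and the stress, cytokine, T cell and muscle lists were lost, 0 with an estimated correlation and 1 with fry.

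With the macrophage score in the fit, all 594 called genes that were tested kept their sign in the fits with another pseudocount, filter or scaling or without 1 library. Without 1 library the count higher was 48 (control 4M) to 620 (control 4F), the count lower 89 to 1049, and the list members called 18 to 124 against 55. The higher and lower counts were 58 and 95 without control 7F, 106 and 217 without Zfp750_KO 2M, 145 and 195 without 3F, 159 and 233 without 6F, and 134 and 302 without 1M. With a log2 difference of at least 1 there were 171 and 295. Array weights gave 405 higher, 636 lower and 91 list members, and a sex term 516, 704 and 98. The fibroblast score or first principal component instead gave the counts above. The 12 lists called became 0 with an estimated correlation, 2 with fry and 9 with the filter of 5 per M, without the stress (adjusted p = 0.0842), wound response (0.0799) and muscle (0.374) lists. The cytokine list lost its call without control 4F (0.0741), the neutrophil list with 4 times the pseudocount (0.0588) and without Zfp750_KO 3F (0.0776), the wound response list with array weights (0.0745) and the first principal component (0.0515), and the mitochondrial list with that component (0.0601) and the fibroblast score (0.105). Zfp750 lost its call with 4 times the pseudocount (-0.98), no filter (-1.39), quantile normalization (-1.34) and the fibroblast score (-1.39), and ranged from -1.64 to -1.02 without 1 library, past the threshold only without Zfp750_KO 6F. Its adjusted p ranged from 0.0198 to 0.267 over all these settings. Beyond fewer libraries or genes, the cause was not tested.

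Directions that turned were all of values not past the threshold in the turned fit. With array weights and the group term alone, Il1b was at -2.12, Nlrc5 at -0.42, Krt71 at 0.039, Il2rb at -0.46, Itgax at -1.50 and the means of the T cell and neutrophil lists at -0.19 and -0.10. Without 1 library Il1b ranged from -0.51 to 2.27, Itgax from -0.29 to 2.48, the proliferation list from -0.34 to 0.027 and Lrig1 from -0.28 to 0.64. The low ends of the first pair and the high end of the list came without control 4F. Lrig1 was at 1.46 with array weights, past the threshold (adjusted p = 0.0403), at -0.073 with a sex term and at -0.11 to 0.35 without 1 library with the macrophage score. The cytokine, hair shaft, T cell, neutrophil and endothelial lists lost their calls without control 4F, and the muscle list without control 7F. Proliferation also lost its call without Zfp750_KO 1M or 2M, with quantile normalization (0.0874), a sex term (-0.087, adjusted p = 0.248) and the first principal component (0.0528), the ribosomal protein list without control 4M, 7F, Zfp750_KO 1M or 2M, the neutrophil list without Zfp750_KO 3F or 6F and with 4 times the pseudocount (0.0688), and the endothelial list without Zfp750_KO 6F.

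No paired analysis was possible because the columns carry no replicate numbers. The planned count tests were not run, as reads came out fractional. In controls, 3 libraries of which 1 had a low macrophage score limit the fit with the score, and 9 to 55 reads of Zfp750 in 6 libraries limit its precision.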

Other observations

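The tests of this part were chosen after the results they examine were seen. For the splits with the gene lists and the fit with a muscle fibre score, the expected outcomes were written down before the test was run, and for the others after. Several myoblast genes outside the lists separated the groups in all libraries, though not every muscle progenitor gene did. Myod1, a master regulator of myoblasts, was at 44.1 to 53.8 in the 3 controls and at 0 to 11.4 in the 4 Zfp750_KO libraries. Cdh15, a cadherin of muscle cells, was at 73.5 to 118 against 10.1 to 25.5, Actc1 at 46.1 to 68.3 against 0 to 8.26, and Pax7, a gene of muscle satellite cells, at 70.9 to 107 against 17.2 to 31.9. With the macrophage score in the limma fit Pax7 had a log2 difference of -1.40 ± 0.20 (SE, adjusted p = 0.00859). Myf5, also of satellite cells, overlapped between the groups, at 10.5 to 28.1 in controls and 0 to 11.3 in Zfp750_KO (adjusted p = 0.25 in the same fit). These genes were picked after their values were seen.

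Postn and Tnc, matrix proteins of wounds, were at 143400 and 57350 in Zfp750_KO 1M and at 137200 and 46450 in 2M. In the other 5 libraries Postn was at 6289 to 15940 and Tnc at 796 to 2883. Neither passed in the limma fit with the macrophage score (adjusted p = 0.396 and 0.0755). That fit assumes the same slope on the score in both groups. Both genes depart from it, as control 4F, with the lowest score, lay among the other 5 libraries. The missing calls therefore do not show that these genes were unchanged.

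Other splits of the 7 libraries into 3 and 4 were fitted in the same way, 35 in all. With the group term alone the real split gave 0 genes past the threshold, which all 35 splits reach, and the highest other split gave 6918. That split sets control 4F, Zfp750_KO 1M and Zfp750_KO 2M against the rest, which points to a structure of the libraries other than genotype. For genes at p under 0.05, 6 of 35 splits gave as many as the real 1058, the highest other 8743, so chance is not excluded. With the macrophage score, the real split alone (1 of 35) gave as many as 594 genes, with 428 as the highest other. The same held for the 228 higher genes (highest other 131) and the 366 lower genes (highest other 297), again 1 of 35 each. These counts are 1 result, since the higher and the lower genes make up the 594, and 1 of 35 is the lowest share that the splits allow. The score was chosen after the real split had given 0 genes without it, so chance is not excluded here either. Without control 4M the real split gave 137 genes. For the lists called by camera chance is not excluded: 22 of 35 splits gave 11 or more with the group term alone, up to 20, and 10 of 35 gave 12 or more with the score, up to 15.

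The lower Zfp750 in Zfp750_KO could come from fewer keratinocytes in those sorts. Against fewer basal keratinocytes, the mean log2 ratio of Zfp750 to Krt5 was -4.76 ± 0.62 (SD) in controls and -6.66 ± 0.94 (SD) in Zfp750_KO. The difference was -1.90, with no overlap of the groups. Krt5 marks basal cells, so the ratio cannot tell about fewer differentiating keratinocytes, which stay open. Krt10, of the cornified envelope list, was at only 0.523 to 11 per M of the library total. All 4 Zfp750_KO libraries lay below the lowest control, but this restates the pattern and cannot decide for the genotype, and the nearest values, 48.9 and 51.2, rest on 47 and 39 reads. Open are the genotype, the reads that remain in Zfp750_KO, since Tbcd spans the gene with means of 542 and 589 normalized in controls and Zfp750_KO, and the smallest p of the design, 0.0571.

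A second pattern is the lower level of Esr1, Cd34, Scara5, Igfbp6, Sfrp4, Ly6a, Mfap5, Spon2 and Aldh1a1, genes known from dermal fibroblasts. A candidate explanation is fewer fibroblasts as a whole. With the macrophage score in the fit, the 9 genes had log2 differences of -2.68 to -0.93. The fibroblast list, which holds Mfap5 too, had a median of -0.11 and quartiles of -0.74 and 0.42, so it did not fall as a whole. The gap between them cannot decide, since the 9 genes were picked for falling. Per M of the library total, the means of Col1a1, Col1a2, Col3a1, Dcn and Sparc were lower in Zfp750_KO and that of Pdgfra higher. Each of these overlapped between the groups, and fewer fibroblasts stay open. With a fibroblast score as a further term, 9 of the 9 genes still passed, as did 8 of the 20 fibroblast list genes and 1892 genes in all. A change within fibroblasts, or in the mix of their subtypes, stays open: in 9 of 9 genes every Zfp750_KO library lay below every control, but the genes were picked for falling, so the count cannot decide.

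The last pattern is the lower level of Myog, Myod1, Cdh15, Mymk and Actc1, which muscle fibres carried over into the control sorts might produce. With a score of 5 muscle fibre genes (Acta1, Ckm, Mylpf, Tnnt3 and Myh4) beside the macrophage score, the median difference of the 5 myoblast genes was -2.43 (median SE 0.74), against -1.84 (median SE 0.26) before. Past the threshold were 1 of 5 genes, against 5 of 5 before, as the SE grew for all 5, Myod1 and Mymk moved toward 0 (-1.83 to -0.91 and -1.23 to -0.68) and the others away from it, which leaves carried-over fibres open. Against them, control 4F held less Acta1 than Zfp750_KO 3F and 6F (138 against 313 and 163), and less Ckm and Myh4 but more Mylpf and Tnnt3, while Myog was higher there (86.7 against 7.89 and 16.5), which rests on 1 control library and excludes nothing. Fewer muscle progenitor cells in the Zfp750_KO sorts may also account for it: Pax7, Myf5 and Megf10 had a median of -1.40, the value of Pax7, but Myf5 (-0.77, adjusted p = 0.25) and Megf10 (-1.63, adjusted p = 0.0603) did not pass, Myf5 overlapped between the groups, and lower transcription per cell gives the same value.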
